A study of Rattus norvegicus with 16 samples.

How the data were processed

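Total RNA from 4 tendons of Sprague Dawley rats was sequenced in 16 libraries, 4 each for the Achilles, patellar, supraspinatus and forepaw flexor tendons. Per the labels, purification used the miRNeasy Micro kit together with DNase I, followed by a standard Illumina library preparation. The deposited count table holds whole-number counts per Ensembl gene, 1 column per library, with no normalization apparent in the values. HISAT2, FastQC, edgeR and the rat genome build rn6 are named in the submitters' processing notes without versions or roles. The counting tool, the annotation release and the strand setting are not given in the sources used here. A further table by the authors gives, per the file headers, the mean log2 CPM of each gene and the log2 fold change of each of the 6 pairs of tendons. Per the file headers it also gives an unadjusted p-value and an adjusted p-value (FDR) for each pair, made by the authors with edgeR. That table lists 12588 of the 23285 genes, and its design and filter are not given in the sources used here.

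Libraries were grouped by the tendon in their labels. Each title ends in the word Rat and a number from 1 to 4, used in every tendon, so that the number may mark an animal shared across tendons or only a library. The labels do not settle which, so no block was fitted, and a fit with a block was run as an alternative. Library totals ran from 63397591 to 102491699 counts, so that 3 counts in a library corresponded to 0.0293 to 0.0473 CPM.

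Genes were filtered with filterByExpr at a minimum count of 10 and a minimum total of 15, which left 16948 genes, and libraries were scaled by TMM. A quasi-likelihood model with 1 coefficient per tendon was fitted to all 16 libraries in edgeR 4.0.16 on R 4.3.3, with 12 residual degrees of freedom. The 6 pairs of tendons, the forelimb against the hindlimb tendons and the difference among all 4 tendons were tested. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Standard errors were taken as the size of the log2 fold change over the square root of F. Means and SDs were computed on TMM-scaled CPM, and log2 CPM used a prior count of 2. The separation of the tendons was tested on the 500 most variable genes by the share of squared distance between groups, over every one of 2627625 partitions into groups of 4.

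Genes were named in the report by a rule fixed before counts were read: an adjusted p under 0.05, a mean of at least 5 CPM in the higher tendon, no overlap between libraries and a gene symbol, taking up to 6 genes per direction by fold change and by p, and examples from the fixed lists. The 4 limb genes of the first look at the labels were fixed with it. Of the genes that met the rule only part are named, picked after the results were seen, as were the most abundant transcripts. The 28 gene lists held 577 symbols, of which 537 were matched to the count table, 5 of them by an older symbol in RefSeq, and 40 are not analysed here. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over all lists and comparisons. The outcome of fry is not reported here. For the closing section, 22 further muscle and 19 further nerve genes outside these lists were chosen after the lists had been tested, when fold changes of Mybpc1, Myom2 and Fa2h had been seen, and 21 and 19 were measured. Genes in families with near-identical copies, such as haemoglobins, myosins and keratins, may share reads. For genes with 3 counts or fewer per library in the lower tendon, levels are given in place of fold changes.

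The alternatives were median-of-ratios size factors, library totals without TMM, DESeq2 1.42.0, limma-voom, no filter and a stricter filter of 1 CPM in 8 libraries. Others were a replicate block, a 2-fold threshold, the mean level of the muscle markers as a covariate, fits of the tendons of a pair alone, and fits without each library in turn. A fit without Achilles 1 and patellar 1, list counts without Achilles 1, list counts with the muscle covariate, and a fit with Achilles 1 as a group of its own were added after the data were seen. The test was tested on simulated data with 200 genes changed between Achilles and patellar tendon. The changed genes had a mean of at least 1 CPM, and counts were drawn once from edgeR's own dispersions, with no library set apart. The edgeR test recovered 26, 60, 90 and 96% of genes changed 1.5, 2, 4 and 8-fold. Of its calls 1.45% were false, against 20.4% with DESeq2 and 2.78% with limma-voom, in data built on edgeR's fit. Every split of the 8 libraries of a pair into groups of 4 was also fitted (35), as were 100 groupings of the 16 libraries. Figures and exact tests used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.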

Results

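RNA abundance was measured by sequencing in 4 tendons of Sprague Dawley rats: the Achilles, the patellar tendon, the flexor tendons of the forepaw and the supraspinatus tendon of the shoulder. Each tendon had 4 libraries of total RNA, 16 in all, and the series was designed to compare each tendon with each of the others. The deposited table gave whole-number counts for 23285 genes. Total counts ranged from 85403509 to 102491699 in the Achilles libraries and from 92673343 to 102130759 in the flexor libraries. They ranged from 63397591 to 74829951 in the patellar libraries and from 81788059 to 101675519 in the supraspinatus libraries. The title of each library ends in the word Rat and a number from 1 to 4, but the labels do not say that the libraries came from separate animals, so the p-values below measure the spread between these samples. Levels are CPM, a gene's counts relative to the TMM-scaled library total, given as mean ± SD over 4 libraries, and fold changes are log2 values ± SE from edgeR's quasi-likelihood test.

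Genes that pattern the limb served as a first look at the labels. Hoxc10 (ENSRNOG00000016149), a HOX gene of the posterior body, stood at 11.9 ± 2.04 CPM in Achilles and 14.9 ± 1.25 CPM in patellar libraries. Its counts in the forepaw flexor libraries were 1 to 2 per library and in the supraspinatus libraries 0 to 4, against 987 to 1393 in the Achilles libraries. Tbx5 (ENSRNOG00000001399), the forelimb T-box factor, was at 29 ± 6.97 CPM in flexor and 12.1 ± 2.58 CPM in supraspinatus tendon. It was at 0.464 ± 0.272 CPM in Achilles tendon but at 5.03 ± 2.67 CPM in patellar tendon, where patellar 1 had 1.06 CPM and the other patellar libraries 6.05 to 6.86. Tbx4 (ENSRNOG00000003544), known from the hindlimb bud, did not follow the limb. It was highest in the forepaw flexors at 31.1 ± 9.93 CPM, then 17.1 ± 10.5 in Achilles, 9.07 ± 4.95 in patellar and 1.08 ± 0.0964 CPM in supraspinatus tendon. Pitx1 (ENSRNOG00000011423), which specifies hindlimb identity in embryos, was at 18 ± 13.2 CPM in Achilles, 15.3 ± 7.25 in patellar and 11.3 ± 4.29 CPM in supraspinatus tendon. Only the forepaw flexors had little of it, at 0.616 ± 0.243 CPM. Floors of 3 counts corresponded to 0.0293 to 0.0473 CPM across the libraries, and such floors cover counting error only.

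**Figure D1:**
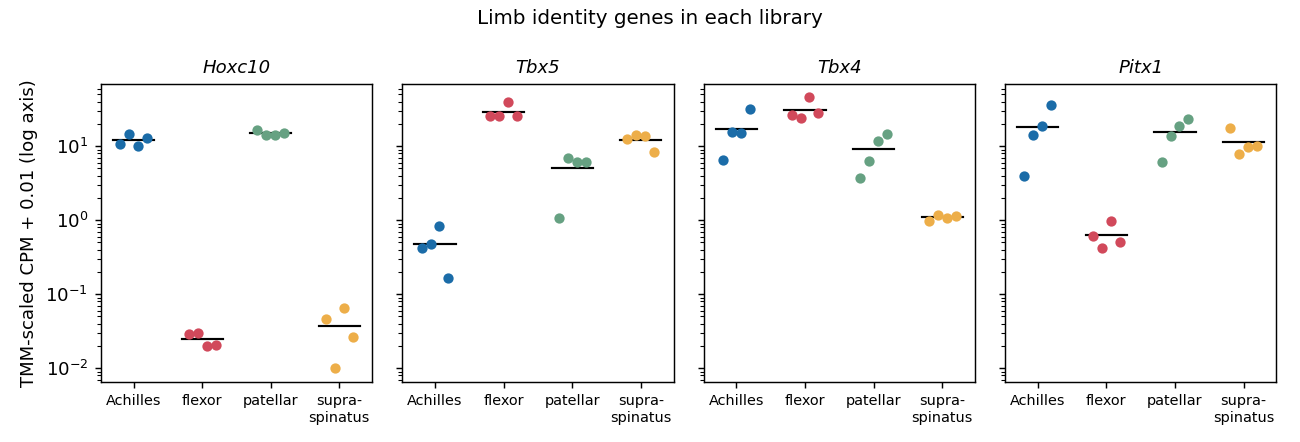
Hoxc10, Tbx5, Tbx4 and Pitx1 in each of the 16 libraries, in TMM-scaled CPM plus 0.01 on a log axis, with 4 points per tendon and a bar at the mean. Hoxc10 separates the hindlimb tendons (9.95 to 16.7 CPM) from the forelimb tendons (0 to 0.0558 CPM), whereas Tbx4 and Pitx1 cross the limbs.

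The most abundant transcripts differed in kind. Col1a1, the main fibrillar collagen chain of tendon, stood at 8.57% of the TMM-scaled library total in Achilles and 7.26% in patellar libraries. In the forepaw flexors it stood at 2.27%, below the actin-severing protein gene Gsn at 4.54%. In supraspinatus tendon Acta1, skeletal muscle actin, came first on average at 5.61%, ahead of Col1a1 at 4.17% and the fast myosin gene Myh4 at 3.7%. On plain library totals Acta1 came first in supraspinatus 1, 3 and 4, at 4.332, 4.228 and 6.038%. In supraspinatus 2 Col1a1 came first at 4.747%. Reads of Myh4 can be shared with near-identical myosin genes, so its level is uncertain.

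Gene expression differed among the 4 tendons. Lgr4, a receptor that amplifies Wnt signals, had the smallest adjusted p of the test among the 4 tendons (1e-10). It stood at 70.6 ± 5.25 CPM in the forepaw flexors and between 6.4 and 7.8 CPM in the other tendons. The glutamate receptor gene Grin2c (adjusted p = 2.6e-10) was likewise a flexor gene, at 12.9 ± 3.25 CPM there, 0.601 ± 0.165 CPM in supraspinatus tendon and 2 to 7 counts per library in the hindlimb tendons. So were Sall1, a zinc-finger factor of the distal limb (11.8 ± 3.91 CPM, adjusted p = 6.3e-09), Ssbp3 (50.5 ± 3.64 CPM, 5.8e-09), Soga1 (30.3 ± 3.14 CPM, 9.1e-09), the channel gene Trpc1 (12 ± 0.991 CPM, 9.1e-09) and the ligand gene Bmp6 (24.2 ± 2.13 CPM, 9.1e-09). Grem1, which encodes a secreted BMP antagonist, was a forelimb gene, at 198 ± 46.2 CPM in flexor and 110 ± 19.6 CPM in supraspinatus against 1.76 ± 0.935 in Achilles and 0.37 ± 0.175 CPM in patellar tendon. Zdhhc1 was highest in supraspinatus tendon at 123 ± 10.1 CPM. Of 16948 genes tested, 12821 differed among the 4 tendons, and 7670 of them spanned at least 2-fold. In the 500 most variable genes the tendon accounted for 77% of the squared distances between libraries, with an exact permutation p of 2.66e-06. Of 2627625 groupings 7, the real one included, had a share as large. That test took the 4 tendons together, so it does not show that Achilles and patellar libraries were separated from each other. Of the 16 libraries 15 had their nearest library in the same tendon, the exception being Achilles 1, which was nearest to patellar 3.

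**Figure D2:**
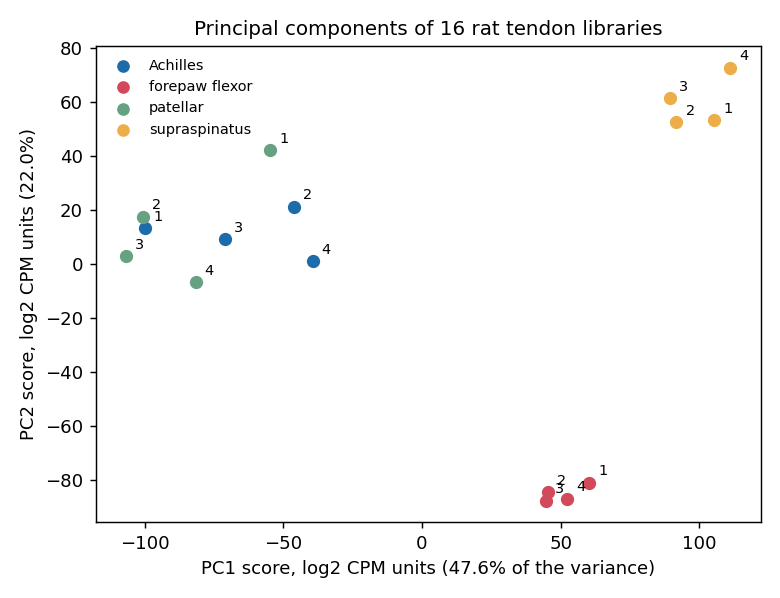
Scores of the 16 libraries on the first principal components of log2 CPM, with 47.57% of the variance on the horizontal and 22.04% on the vertical axis, coloured by tendon and numbered by replicate. The forelimb tendons lie apart from each other and from the Achilles and patellar libraries, which adjoin.

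Gene lists fixed before the data were examined show how broad these differences were. Of all genes tested 75.6% differed among the tendons, so a count near that share is not particular to its list. The shares of the lists ran from 54.5% for keratinocyte and skin markers to 100%. All measured members differed among the tendons in the lists of oxidative phosphorylation (28), cell cycle (19), endothelial markers (15), osteoblast and osteocyte markers (13), mast cell and granulocyte markers (13), fast skeletal muscle markers (12) and slow and general skeletal muscle markers (20). So did 33 of 35 limb identity and HOX genes, 16 of 17 glycolysis genes, 15 of 16 adipocyte markers, 25 of 27 Wnt pathway genes and 31 of 34 genes of matrix glycoproteins and elastic fibres. The count was 8 of 9 for satellite cell and myogenic markers, 6 of 7 for erythroid markers, 12 of 14 for Schwann cell and nerve markers, 23 of 28 for proteoglycans and 9 of 11 for lymphocyte markers. It was 15 of 19 for chondrocyte markers, 11 of 14 for tendon fibroblast genes, 29 of 37 for TGF-beta, BMP, FGF and IGF ligands, 7 of 9 for synovial lining markers and 29 of 38 for matrix proteases, inhibitors and crosslinking enzymes. Members also differed among other collagens (22 of 30), pericyte and smooth muscle markers (9 of 13), fibrillar collagens (7 of 11), immediate early and heat shock genes (14 of 24), macrophage and monocyte markers (9 of 16) and keratinocyte and skin markers (6 of 11). Adjusted over the list alone, the proteases numbered 30, the macrophage markers 8 and the keratinocyte markers 5, and each of the other counts was the same.

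Skeletal muscle genes marked the supraspinatus libraries. The 32 measured muscle markers took 16.4 ± 3.25% of the counts there, with a range of 13.1 to 20.6%. Their share was 4.7 ± 2.22% in the forepaw flexors, 1.79 ± 1.91% in patellar and 1.29 ± 0.618% in Achilles tendon. Patellar 1 had 4.66% where the other patellar libraries had 0.764 to 0.946%. The marker Car3 ran against this order, at 5210 ± 1980 CPM in patellar and 3948 ± 1470 CPM in Achilles tendon. It was at 1355 ± 597 CPM in supraspinatus and 478.5 ± 196 CPM in flexor tendon. The muscle shares of the hindlimb tendons, also where cited below, thus rest in part on a gene without the muscle pattern. What Car3 marks in these tendons was not tested. The TMM factors of the supraspinatus libraries were 0.7312 to 0.8763, while those of the other tendons exceeded 1. Without TMM, on library totals alone, the median log2 fold change of all genes moved by 0.41 in Achilles and in patellar against supraspinatus, by 0.34 in flexor against supraspinatus and by -0.24 in forelimb against hindlimb. The changes reported here are relative to the TMM scale.

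**Figure D3:**
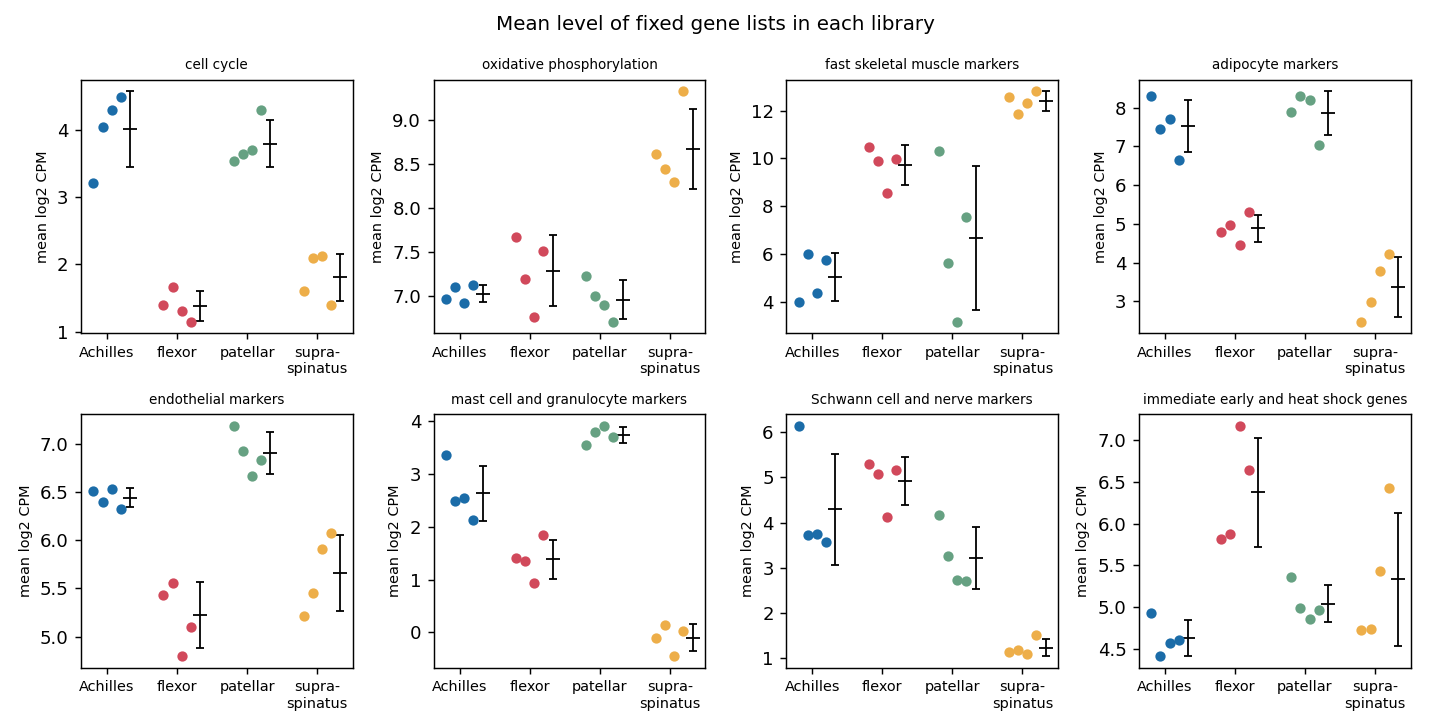
Mean log2 CPM of 8 of the fixed gene lists in each library, 4 points per tendon, with the mean and SD beside them. Cell cycle genes averaged 4.01 and 3.80 in Achilles and patellar tendon against 1.38 and 1.81 in flexor and supraspinatus tendon, and 1 Achilles library (6.14) stands above the others in the nerve list.

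**Figure D4:**
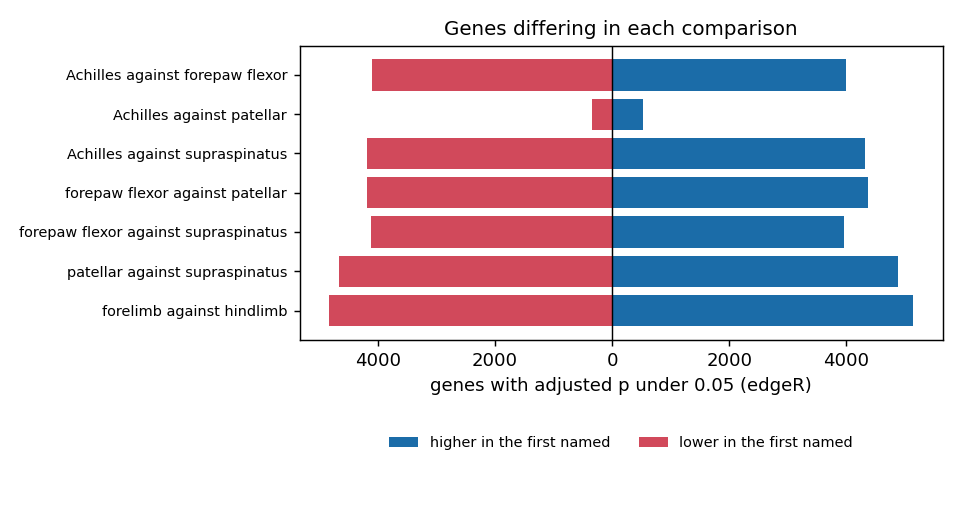
Number of genes with an adjusted p under 0.05 in edgeR's quasi-likelihood test for each comparison, with genes higher in the first-named tendon to the right and lower ones to the left of 0. Achilles against patellar gave 874 genes, while the other comparisons gave between 8076 and 9971.

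Forelimb tendons were first set against hindlimb tendons, as the average of the log2 levels of flexor and supraspinatus against that of Achilles and patellar. Grem1 was higher in the forelimb tendons by a log2 fold change of 7.51 ± 0.31 (adjusted p = 2e-09). Matrix genes on the same side were Cilp, a cartilage matrix protein (2.23 ± 0.17), the proteoglycan gene Vcan (2.30 ± 0.20) and Prelp (1.98 ± 0.15), and the Wnt antagonist gene Frzb was higher as well (3.58 ± 0.33). Tppp3, a marker of tendon sheath cells, was higher by 2.08 ± 0.12, as were the small heat shock gene Hspb1 (1.72 ± 0.15), the phosphatase gene Dusp1 (2.05 ± 0.23) and Musk (2.41 ± 0.28), which organises the neuromuscular junction. The hindlimb tendons had more periostin (Postn, log2 fold change -3.37 ± 0.29), Igf1 (-2.29 ± 0.11), Mest (-3.52 ± 0.16), Angpt4 (-5.06 ± 0.23), Srpx (-2.45 ± 0.12), the Wnt modulator Sfrp2 (-3.94 ± 0.35), the protease gene Mmp23 (-2.68 ± 0.17) and Col18a1 (-1.94 ± 0.16). Albumin (Alb) counts were at 11 ± 2.66 CPM in Achilles and 11.5 ± 7.03 CPM in patellar tendon and did not exceed 6 counts in a forelimb library.

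All 19 cell cycle genes were lower in the forelimb average, with a median log2 fold change of -2.67, among them Mcm5 (-2.77 ± 0.15) and Tyms (-1.67 ± 0.092), while the cyclin gene Ccnd2, outside the list, differed by -1.42 ± 0.065. Not every gene was lower in both forelimb tendons. Tpx2, on the list, was at 3.78 CPM in flexor but 23.3 in supraspinatus, against 16.7 in Achilles and 15.7 CPM in patellar tendon. The camera test with a preset correlation gave an adjusted p of 9.77e-11 for this list, and 0.537 with an estimated correlation. Adipocyte markers (14 of 16 lower in the forelimb, 15 adjusted over the list alone) included adipsin (Cfd, -5.06 ± 0.35) and leptin (Lep, -6.37 ± 0.46). All 15 endothelial markers were lower in the forelimb average, among them Erg (-1.48 ± 0.12), as were all 13 mast cell and granulocyte markers, with Mpo at -6.51 ± 0.49 and S100a9 at -3.83 ± 0.31. So were 9 of 11 lymphocyte markers and 6 of 7 erythroid markers, although reads of haemoglobin genes can be shared between near-identical copies. The mast cell marker Tpsb2 was low in supraspinatus only, at 2.32 CPM, against 19.4 in flexor, 17.8 in Achilles and 33.2 CPM in patellar tendon. Higher in the forelimb average were 14 of 24 immediate early and heat shock genes (5 with the muscle covariate), more through the flexors than through the supraspinatus. Flexor tendon had 16 of them higher than Achilles and 13 higher than patellar tendon, and supraspinatus tendon had 9 higher than Achilles tendon. Against patellar tendon supraspinatus had 4 higher and 1 lower (3 and 0 adjusted over the list alone, 0 and 0 with the muscle covariate), and on library totals 2 higher and 6 lower, where the patellar median turned from -0.40 to 0.03. Dusp1 stood at 1310 ± 436 CPM in flexor but at 207 ± 48.9 in supraspinatus, 158 ± 48.7 in patellar and 101 ± 45 CPM in Achilles tendon. The 28 oxidative phosphorylation genes and 13 of 17 glycolysis genes were also higher in the forelimb average, beside muscle shares of 4.7 and 16.4% against 1.29 and 1.79%. With the muscle marker score as a covariate the oxidative phosphorylation count was 0 and the glycolysis count 7, while 18 cell cycle, 12 adipocyte and 13 endothelial genes were still lower. Camera adjusted p-values for these lists all exceeded 0.05 once the correlation was estimated, the smallest being 0.537, in this comparison and in each of the 6 pairs.

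Across the limbs 9971 genes differed, 5140 higher and 4831 lower in the forelimb tendons. On library totals the higher share was 31.1% in place of 51.5%, and with the muscle covariate 3275 genes differed. The other ways of averaging the tendons gave 6077 genes (Achilles and flexor against patellar and supraspinatus) and 6379 genes (Achilles and supraspinatus against flexor and patellar). Tbx5 was higher in the forelimb average (3.61 ± 0.36) and Pitx1 lower (-2.65 ± 0.40). Pitx1 was lower through the flexors alone, at 0.616 CPM. In supraspinatus tendon it did not differ from Achilles (adjusted p = 0.3) or patellar tendon (adjusted p = 0.5). Tbx4, highest in flexor (31.1 CPM) and lowest in supraspinatus tendon (1.08 CPM), gave -1.10 ± 0.31 (adjusted p = 0.0073) through the low supraspinatus level, so that it was not lower in both forelimb tendons. It did not pass with limma-voom (-0.90, adjusted p = 0.0743) or with the muscle covariate (-1.40, adjusted p = 0.173), where the fold stayed on the same side.

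Achilles and forepaw flexor tendon differed in patterning, Wnt pathway, cell cycle, fat and muscle genes, among others. Hoxd13, a HOX gene of the digits, was at 17.5 ± 3.32 CPM in the flexors and 0 to 6 counts in an Achilles library. Isl1, a homeobox gene of the hindlimb field, was at 20.7 ± 5.34 CPM in Achilles tendon and 1 to 7 counts in a flexor library, and Hoxc10 likewise was nearly restricted to Achilles tendon in this pair. Grem1 (-6.81 ± 0.42), Lgr4 (-3.46 ± 0.13, adjusted p = 9.9e-10), Trpc1 (-2.46 ± 0.14), Bmp6 (-3.59 ± 0.22), Wnt11 (-3.31 ± 0.34), Frzb (-4.83 ± 0.49) and Cilp (-3.03 ± 0.25) were lower in Achilles than in flexor tendon, and Grin2c was at 3 to 7 counts per Achilles library. Postn (3.78 ± 0.41), the pregnancy-associated protease gene Pappa2 (4.11 ± 0.25), Mmp23 (2.95 ± 0.24), the fatty acid binding gene Fabp5 (2.62 ± 0.15) and the collagen gene Col1a1 (1.91 ± 0.34) were higher. Col1a2 was higher too (1.86 ± 0.37), but its counts were far below those of Col1a1 (237 against 85700 CPM in Achilles tendon), so what they measure is uncertain. Htra3, a protease gene, was lower (-2.05 ± 0.51).

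Cell cycle and stress genes parted this pair as well. All 19 cell cycle genes were higher in Achilles tendon, with a median of 2.67, Mcm5 at 3.38 ± 0.22 and Ccnd2 at 1.46 ± 0.092. Of the immediate early and heat shock genes 16 of 24 (17 adjusted over the list alone) were lower, including Egr1, a factor that drives tendon collagen genes (-2.73 ± 0.37), and Dusp1 (-3.70 ± 0.35), and 10 were lower with the muscle covariate. Adipocyte markers were higher in Achilles tendon for 14 of 16 genes (15 adjusted over the list alone, median 2.91), endothelial markers for 12 of 15 (14 adjusted over the list alone, median 1.23), lymphocyte markers for 5 of 11 and erythroid markers for 4 of 7 (5 adjusted over the list alone). All 12 fast skeletal muscle markers (median -4.27) and 7 of 9 satellite cell and myogenic markers (median -2.89, 4 with the muscle covariate) were lower, whereas 4 of 20 slow and general muscle markers were higher and 3 lower (2 and 0 adjusted over the list alone, 5 and 1 without Achilles 1, 7 and 0 with the muscle covariate). Of the Wnt pathway genes 17 of 27 (18 adjusted over the list alone) were lower and 3 higher, and of the ligands of the TGF-beta, BMP, FGF and IGF families 15 of 37 were lower and 5 higher. Schwann cell and nerve markers gave 1 higher and 1 lower gene of 14, but without Achilles 1 there were 8 lower ones. In all, 8076 genes differed, 3987 higher and 4089 lower in Achilles tendon. Tbx5 was lower (-5.96 ± 0.57) and Pitx1 higher (4.86 ± 0.62). Tbx4 did not pass (-0.86 ± 0.43, adjusted p = 0.11), though it did with limma-voom (0.0314), with a replicate block (0.024) and without Achilles 4 (0.0174).

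Achilles and patellar tendon were the closest pair. Stromelysin genes Mmp3 (3.73 ± 0.29, adjusted p = 3.2e-05) and Mmp10 (3.44 ± 0.31) were higher in Achilles tendon, as was lubricin (Prg4, 3.63 ± 0.33, adjusted p = 6.7e-05), a surface lubricant made by synovial and sheath cells, at 1280 ± 542 CPM against 103 ± 41.6 CPM. Secreted proteins Vit (2.39 ± 0.24), Serpina1 (4.03 ± 0.42), Lbp (3.06 ± 0.34), Matn2 (1.33 ± 0.17) and Thbs3 (1.09 ± 0.19) and the lipase gene Pla1a (1.65 ± 0.19) were also higher, together with the integrin gene Itgb8 (2.22 ± 0.37). Higher in patellar tendon were regulators of regional identity: Lhx9 (-5.15 ± 0.45, adjusted p = 5.6e-05), Emx2 (-3.47 ± 0.34), Osr2 (-2.40 ± 0.29) and Hoxc6 (-2.43 ± 0.26), with the ligand genes Bmp7 (-4.93 ± 0.70) and Wnt2 (-3.17 ± 0.50), the oxidase gene Nox4 (-2.10 ± 0.25) and Car8 (-2.11 ± 0.21). Isl1 ran the other way and was higher in Achilles tendon, at 20.7 ± 5.34 CPM against 0.215 ± 0.396 CPM (0 to 57 counts in a patellar library). Of 35 limb identity and HOX genes 11 were lower and 2 higher in Achilles tendon (13 and 2 adjusted over the list alone).

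In this pair 874 genes differed, 525 higher and 349 lower in Achilles tendon. In simulated data for this comparison the test recovered 60% of genes changed 2-fold and 90% of those changed 4-fold. The changed genes there had at least 1 CPM, so recovery of the lower genes tested is not known. The count moved with single libraries, to 342 without Achilles 2, 480 without Achilles 3, 403 without patellar 2, 360 without patellar 3, 463 without patellar 4 and 1415 without patellar 1. It was 268 in a fit of these 8 libraries alone and 1977 with DESeq2. Slow muscle troponin Tnni1 was higher in Achilles tendon (6.04 ± 1.2, adjusted p = 0.014), with an SD of 245 CPM around 260 CPM, but did not pass with limma-voom (4.71, adjusted p = 0.192), the muscle covariate (3.73, 0.173) or these 8 libraries alone (6.03, 0.0843). Tbx5 was lower (-3.43 ± 0.52) and Grem1 higher (2.23 ± 0.39) in Achilles tendon, but with these 8 libraries alone neither passed (-3.44 and 2.24, adjusted p = 0.0516 and 0.0667). Hoxc10 (adjusted p = 0.41), Tbx4 (0.23) and Pitx1 (0.83) did not differ beyond the spread. Of the synovial lining markers 3 of 9 were higher (4 adjusted over the list alone), as were 3 of 28 proteoglycans (5 adjusted over the list alone). Slow and general muscle markers were higher in Achilles tendon for 7 of 20 genes (11 adjusted over the list alone, 1 with the muscle covariate), and fast muscle markers were lower for 3 of 12 (6 adjusted over the list alone). The fast markers took 0.0168 to 2.42% of counts over the patellar libraries. Patellar 1 stood apart there, with a share of 4.66% for all muscle markers.

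Achilles and supraspinatus tendon differed in muscle, fat and nerve genes, among others. Neprilysin (Mme, 3.88 ± 0.20, adjusted p = 6.8e-08), the membrane glycoprotein gene Gpm6b (3.79 ± 0.21), the oxytocin receptor gene Oxtr (7.28 ± 0.46), Mmp3 (4.14 ± 0.29), Mmp23 (3.02 ± 0.24), Igf1 (2.47 ± 0.16) and the microfibril gene Mfap2 (2.54 ± 0.35) were higher in Achilles tendon. Grem1 (-5.97 ± 0.40), Vcan (-2.79 ± 0.29), Prelp (-1.98 ± 0.22), Zdhhc1 (-1.69 ± 0.090), cartilage collagen Col2a1 (-4.94 ± 0.79), Wif1 (-4.93 ± 0.79) and Abi3bp (-1.13 ± 0.24) were higher in supraspinatus tendon. Adipocyte markers were higher in Achilles tendon for 14 of 16 genes, with Cfd at 5.94 ± 0.52 and Lep at 7.92 ± 0.70. Of 14 Schwann cell and nerve markers 13 were higher (14 adjusted over the list alone), including the glial factor Sox10 (3.71 ± 0.36) and Ngfr (3.28 ± 0.39), and 11 were higher without Achilles 1. Mast cell and granulocyte markers were higher for 12 of 13 genes and cell cycle genes for 18 of 19, with Mcm3 at 2.15 ± 0.16.

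The 28 oxidative phosphorylation genes, such as Ndufs1 (-2.24 ± 0.29), and 11 of 17 glycolysis genes, such as Pkm (-2.25 ± 0.25), were lower in Achilles tendon, beside muscle shares of 1.29% and 16.4%. With the muscle covariate the counts were 1 and 7, and 17 cell cycle and 2 nerve genes passed. Col2a1 (-3.74), Wif1 (-2.98), Mfap2 (1.71), Abi3bp (-0.58) and Ndufs1 (-1.32) kept their side with that covariate but did not pass (adjusted p from 0.0542 to 0.339). In this pair 8497 genes differed, 4312 higher and 4185 lower in Achilles tendon, and 2055 with the muscle covariate. The higher share was 50.7%, or 78.7% on library totals. Tbx5 was lower (-4.70 ± 0.54) and Tbx4 higher (3.98 ± 0.49) in Achilles tendon, Hoxc10 was nearly restricted to it in this pair, and Pitx1 did not pass (adjusted p = 0.3).

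Forepaw flexor and patellar tendon differed in HOX genes in both directions. Hoxd13 (17.5 ± 3.32 CPM), Hoxd11 (5.11 ± 0.856 CPM) and Sall1 (11.8 ± 3.91 CPM) were flexor genes with at most 2 counts in a patellar library. Hoxc8, at 12.5 ± 1.8 CPM in patellar tendon, had at most 2 counts in a flexor library, and Hoxc6 was lower in flexor tendon by -6.19 ± 0.32 (adjusted p = 2.9e-08), alongside Hoxc10. Grem1 (9.05 ± 0.47), Lgr4 (3.18 ± 0.12), Bmp6 (3.96 ± 0.23), Trpc1 (2.43 ± 0.14), Frzb (5.43 ± 0.51), Cilp (3.44 ± 0.25), Prg4 (3.59 ± 0.32) and Egr1 (2.07 ± 0.36) were higher in flexor tendon, and Grin2c had 2 to 5 counts per patellar library. Postn (-5.03 ± 0.44), Sfrp2 (-5.70 ± 0.54), Pappa2 (-5.02 ± 0.26), Mest (-4.21 ± 0.24), Angpt4 (-5.37 ± 0.32), the neutrophil gene Mpo (-7.15 ± 0.70) and the collagens Col1a1 (-1.67 ± 0.34) and Col3a1 (-1.26 ± 0.28) were lower. With the muscle covariate Col3a1 (-0.67) did not pass (adjusted p = 0.139).

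All 19 cell cycle genes were lower in the flexors (median -2.54), as were 14 of 15 endothelial markers (15 adjusted over the list alone), 15 of 16 adipocyte markers and 10 of 11 lymphocyte markers. Of 27 Wnt pathway genes 16 were higher and 4 lower, or 6 lower adjusted over the list alone. Of 35 limb identity and HOX genes 9 were higher and 22 lower, or 23 lower adjusted over the list alone. The comparison gave 8560 genes, 4372 higher and 4188 lower in flexor tendon, and 5595 with the muscle covariate. Tbx5 (2.53 ± 0.48) was higher and Pitx1 (-4.63 ± 0.62) lower in flexor tendon. Tbx4 was higher (1.78 ± 0.44), and with the muscle covariate it was at 1.52 and did not pass (adjusted p = 0.105).

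Forepaw flexor and supraspinatus, both tendons of the forelimb, differed in patterning genes in both directions. Of 35 limb identity and HOX genes 13 were higher and 14 lower in flexor tendon (14 and 16 adjusted over the list alone). Hoxd13 and Sall1 had at most 5 counts in a supraspinatus library. Hoxc5 (-4.89 ± 0.29), Hoxc6 (-5.34 ± 0.31) and the homeobox genes Meis1 (-2.76 ± 0.22) and Meis2 (-3.72 ± 0.31) were lower in flexor tendon. Lgr4 (3.28 ± 0.13, adjusted p = 1.9e-09), Ssbp3 (2.52 ± 0.11), the Polycomb gene Phc2 (2.43 ± 0.13), Bmp6 (3.25 ± 0.22), the activin gene Inhbb (4.09 ± 0.39), Sfrp1 (3.77 ± 0.35), Dkk2 (3.21 ± 0.31), Egr1 (2.43 ± 0.37), Spock1 (5.91 ± 0.76), Mmp3 (3.11 ± 0.28) and Mmp10 (3.0 ± 0.31) were higher. Col2a1 (-7.23 ± 0.88), Dmp1, a gene of bone mineral (-2.74 ± 0.52), Pappa2 (-3.66 ± 0.25) and Abi3bp (-2.06 ± 0.24) were lower. Col2a1 varied widely in supraspinatus tendon, at 1760 ± 1780 CPM.

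Nerve genes Sox10 (4.96 ± 0.38) and the myelin gene Mbp (5.81 ± 0.92) were higher in flexor tendon, with 12 of 14 genes of their list. Of 27 Wnt pathway genes 17 were higher and 4 lower, and of 37 ligands 18 were higher (19 adjusted over the list alone) and 5 lower. The 28 oxidative phosphorylation genes, among them Cox6b1 (-1.60 ± 0.19), were lower, beside muscle shares of 4.7% and 16.4%, and all 28 were lower with the muscle covariate too. Also lower were 10 of 17 glycolysis genes (11 adjusted over the list alone), 8 of 20 slow and general muscle markers (11 without Achilles 1) and 3 of 12 fast ones. With the covariate, which is built from these markers, 5 slow and general ones were higher and 2 lower and no fast one passed. Cell cycle genes gave 5 lower genes of 19, with a median of -0.16 that became 0.17 on library totals. In all, 8082 genes differed, 3964 higher and 4118 lower in flexor tendon, with a higher share of 49% that became 78.3% on library totals. Tbx4 was higher (4.85 ± 0.51), Pitx1 lower (-4.19 ± 0.61) and Hoxc10 did not pass (adjusted p = 0.35). Tbx5 passed narrowly (1.26 ± 0.46, adjusted p = 0.035). It did not pass with the muscle covariate (0.36, adjusted p = 0.643). Nor did it pass, at folds of 1.02 to 1.34, without any 1 flexor library (0.0568, 0.0596, 0.11 and 0.0592 for libraries 1 to 4), without any 1 supraspinatus library (0.0584, 0.0519, 0.0573 and 0.0854) or without Achilles 2 (0.0527).

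Between patellar and supraspinatus tendon, Mme (4.22 ± 0.21, adjusted p = 2.2e-08), Angpt4 (6.25 ± 0.34), Bcl3 (3.01 ± 0.18), Igf1 (2.50 ± 0.16), Hoxb7 (3.72 ± 0.24), Postn (2.95 ± 0.40) and the mast cell protease gene Cpa3 (4.91 ± 0.41) were higher in patellar tendon. Mmp27 was at 40.5 ± 14.9 CPM there and at 0 to 6 counts in a supraspinatus library, and Hoxc10 too was nearly restricted to patellar tendon in this pair. Higher in supraspinatus tendon were Grem1 (-8.20 ± 0.46), Tppp3 (-2.73 ± 0.17), Ezr (-1.99 ± 0.13), Chodl (-4.44 ± 0.46), Prelp (-2.27 ± 0.22), Prg4 (-2.97 ± 0.32), Wnt16 (-4.05 ± 0.53), the matricellular gene Thbs4 (-2.21 ± 0.36), the chondrocyte factor Sox6 (-2.43 ± 0.23) and the collagens Col24a1 (-2.43 ± 0.27) and Col2a1 (-5.21 ± 0.80). Metabolic genes Pkm (-2.18 ± 0.25) and Ndufs1 (-2.37 ± 0.29) were also higher in supraspinatus tendon, beside muscle shares of 1.79% and 16.4%.

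All 13 mast cell and granulocyte markers, 14 of 16 adipocyte markers, 13 of 15 endothelial markers and 18 of 19 cell cycle genes, such as Tyms (1.72 ± 0.13), were higher in patellar tendon. Nerve markers were higher for 8 of 14 genes, Sox10 among them (3.49 ± 0.36), and 6 of 9 synovial lining markers were lower (7 adjusted over the list alone). The 28 oxidative phosphorylation genes and 13 of 17 glycolysis genes (14 adjusted over the list alone) were lower, beside muscle shares of 1.79% and 16.4%. With the muscle covariate these counts were 3 and 5, and 15 cell cycle genes passed. With that covariate Thbs4 (-1.76), Col2a1 (-3.60), Postn (1.73) and Ndufs1 (-1.34) kept their side but did not pass (adjusted p from 0.0649 to 0.16). The pair gave 9555 genes, 4887 higher and 4668 lower in patellar tendon, and 2146 with the muscle covariate. The higher share was 51.1%, or 77% on library totals. Tbx4 was higher in patellar tendon (3.07 ± 0.48) and Pitx1 did not pass (adjusted p = 0.5). Tbx5 was lower (-1.27 ± 0.46, adjusted p = 0.03), but did not pass on library totals (-0.88, adjusted p = 0.113), with these 8 libraries alone (-1.27, 0.0505) or without supraspinatus 1 (0.0591), 2 (0.0641) or 3 (0.0595).

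The authors' deposited table of the 6 pairs listed 12588 genes. At an adjusted p under 0.05 it called 6382 genes for Achilles against flexor, 797 for Achilles against patellar, 6871 for Achilles against supraspinatus, 7269 for flexor against patellar, 7392 for flexor against supraspinatus and 8097 for patellar against supraspinatus. A fit of the same genes with all 16 libraries in their tendons gave log2 fold changes that differed from the table by an SD of up to 0.313 in a pair. A fit in which Achilles 1 formed a group of its own differed from it by at most 4.3e-09 in log2 fold change and 4.7e-09 in mean log2 CPM. That fit called 6399, 804, 6885, 7280, 7404 and 8108 genes in the same order, of which 6375, 796, 6864, 7261, 7389 and 8087 were also called in the deposited table. The deposited fold changes of Achilles tendon thus rest on Achilles 2, 3 and 4, whereas the values above include Achilles 1.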

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

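Of the tests in this part, those of scaling, of blood cell markers, of a wrong label on Achilles 1 and of further nerve genes were set before their results were seen, and the others only after. For 59 measures in each of 4 tendons, the gap between the most distant library and its nearest neighbour was divided by the range of the 4 libraries. Of these 236 groups 15 lay past the 95% critical value, where chance gives about 1 in 20, or 11.8.

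Achilles 1 stood apart in the mean log2 CPM of nerve markers (6.138 against 3.573 to 3.754, ratio 0.929), erythroid markers (2.908 against 2.384 to 2.462, ratio 0.85) and lymphocyte markers (-0.535 against -0.992 to -0.918, ratio 0.837), and in the log2 CPM of Isl1 (3.678 against 4.51 to 4.608, ratio 0.894). Patellar 1 stood apart in the muscle share (4.66% against 0.764 to 0.946%, ratio 0.953), in glycolysis genes (7.04 against 6.123 to 6.217, ratio 0.898), in Tbx5 (0.112 against 2.601 to 2.784, ratio 0.932) and in Hoxd13 (ratio 1), where it had 2 counts and the other patellar libraries 0. Patellar 2 had no Hoxd11 counts where the others had 1 each (ratio 0.936), and patellar 4 had more Soga1 (3.089 against 2.563 to 2.624, ratio 0.884).

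Among the flexor libraries, flexor 3 stood apart in Tbx5 (5.302 against 4.66 to 4.695, ratio 0.945), Mmp27 (0.141 against 2.42 to 2.747, ratio 0.874), synovial lining markers (6.081 against 5.931 to 5.953, ratio 0.852) and genes with a count (19630 against 19720 to 19740, ratio 0.905). Flexor 2 was higher in fibrillar collagens (7.919 against 7.686 to 7.721, ratio 0.849).

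Skeletal muscle transcripts were high in the supraspinatus libraries. Scaling does not account for this, since on library totals the muscle genes still had a median log2 difference of at least 1.95 from each other tendon. A single mislabelled library does not account for it, because all 4 supraspinatus libraries had a share of at least 13.1% and the highest share in another tendon was 7.22%. Skeletal muscle tissue in the samples remains open, with 21 of 21 further muscle genes, on none of the fixed lists, higher in supraspinatus than in patellar tendon. Whether such tissue belongs to the tendon or came with its dissection could not be told from these counts.

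Cell cycle genes were lower in the average of the forelimb tendons. With the muscle covariate 18 of 19 genes were still lower, but muscle shares differed between the tendons, so this alone cannot exclude dilution by muscle RNA. The muscle share, at most 20.6% in a library, covers 32 marker genes and not all muscle RNA. It was 4.7 ± 2.22% in flexor and 16.4 ± 3.25% in supraspinatus tendon. The cell cycle genes nevertheless averaged 1.38 ± 0.218 log2 CPM in flexor and 1.81 ± 0.356 in supraspinatus tendon. These values argue against dilution as the whole cause. Blood or bone marrow cells in the hindlimb samples stay open: within tendons, cell cycle and blood cell markers had r = -0.257 over 8 libraries (exact permutation p = 0.523, Spearman 0.0238). A difference between the tendons in dividing cells also stays open and was not tested.

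Achilles 1 lay nearest to a patellar library. A share of genes could not by itself exclude a wrong label in place of patellar, because the share that a rightly labelled library gives was not measured. The value leaned against such a label. Of the genes that separated the tendons without Achilles 1 and patellar 1, 66.4% had Achilles 1 nearer the other Achilles libraries. These were 1379 of 1381 genes, those that passed the filter over all 16 libraries. For a swap with patellar 1, patellar 1 lay nearer its own tendon in 54.9% of these genes, which alone decides little, but a swap needs both libraries out of place. That reading was set after both values were known. Counts of patterning genes argue against a wrong label and against a swap. Isl1 had 1442 to 2258 counts in the Achilles libraries, Achilles 1 included, against 0 to 57 in the patellar libraries. Lhx9 had 6 to 31 against 367 to 495, Hoxc6 109 to 121 against 419 to 583 and Hoxc8 230 to 306 against 814 to 1082. These genes were picked after the results were seen, with Achilles 1 in its labelled group. Nerve tissue in the sample remains open, with 18 of 19 further nerve genes, on none of the fixed lists, highest in Achilles 1 among the Achilles libraries.

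Other splits of the same libraries were refitted to see whether chance assignment gives as many genes. In 5 pairs only 1 of 35 splits, the real one, reached its count. Counts were 8076 against at most 55 for Achilles and flexor, 8497 against 0 for Achilles and supraspinatus and 8560 against 20 for flexor and patellar. They were 8082 against 52 for flexor and supraspinatus and 9555 against 0 for patellar and supraspinatus. This argues against chance in each pair, but 35 splits cannot give a share below 1 of 35. The other splits also mixed tendons within a group, which widens the spread and lowers their counts. Among the 4 tendons 1 of 100 groupings, the real one, reached the count (12821 against 2113), which argues against chance among the tendons. The same held for the limb contrast (9971 against 6). These groupings shuffled libraries over all 4 tendons, so they test for any tendon difference and not for a limb effect. Each limb had only 2 tendons, and the other averages of the tendons gave 6077 and 6379 genes. Chance thus cannot be excluded for the limb. For Achilles and patellar, 2 of 35 splits reached 874, so chance cannot be excluded at that level. The other split gave 1489 genes and put patellar 1 with Achilles 1, 2 and 3 and Achilles 4 with the remaining patellar libraries. In a fit of these 8 libraries alone, added later, that split gave 0 genes, the real split 268 and the highest other 10, so the count of 1489 depends on the fit with all 16 libraries.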

How the results depend on the processing

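Among the settings below, the fit without both Achilles 1 and patellar 1 was chosen after the data were seen. A threshold of 2-fold left 7670 genes among the 4 tendons, 4106 for Achilles and flexor, 398 for Achilles and patellar, 4228 for Achilles and supraspinatus, 4498 for flexor and patellar, 3940 for flexor and supraspinatus, 4883 for patellar and supraspinatus and 3890 between the limbs, fewer by its own construction. The muscle covariate gave 2055 genes for Achilles and supraspinatus, 5595 for flexor and patellar, 2146 for patellar and supraspinatus and 3275 between the limbs. Muscle shares differed between these tendons, so that covariate takes part of the tendon difference with it. Other averages of the tendons gave 6077 and 6379 genes in place of 9971.

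Achilles and patellar gave 1977 genes with DESeq2, 268 with these tendons alone and 1381 without Achilles 1 and patellar 1, and the cause was not tested. DESeq2 called more false genes in the simulated data, which were drawn from edgeR's own dispersions. Without 1 library the edgeR count for Achilles and patellar ran from 342 (without Achilles 2) to 1415 (without patellar 1). It was 480 without Achilles 3 and 403, 360 and 463 without patellar 2, 3 and 4. The other counts stayed within 1.5 times without any 1 library: 12402 to 13135 among the 4 tendons, 7223 to 8501, 7601 to 8826, 7542 to 8951, 6905 to 8602 and 8730 to 9938 in the other pairs in the order above, and 9532 to 10081 between the limbs. The separation share was 72.61 to 77.03% under other gene sets and scaling and 75.51 to 81.94% without 1 library.

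Of 197 results for named genes, 14 lost their call with the muscle covariate, 4 with the tendons of the pair alone and 2 without 1 library. Pitx1 in Achilles against patellar, which did not pass the threshold (0.24), changed sign with limma-voom (-0.0295) and with the muscle covariate (-0.0379), and ran from -0.33 to 0.57 without 1 library. The cause was not tested. Pitx1 in Achilles against supraspinatus passed without Achilles 1 and patellar 1 (adjusted p = 0.0307).

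With a replicate block, 12629 genes differed among the 4 tendons, 9942 between the limbs and 8026, 836, 8356, 8699, 8064 and 9434 in the 6 pairs. Of 24 same-numbered pairs of libraries from different tendons 9 had r over 0.1 (range -0.21 to 0.37), with a mean of 0.0574 against -0.019 for different numbers. Of the 16 libraries 10, not all, correlated best with a library of their own number, though 24 pairs shared a number and 72 did not. This is a hint of pairing from the data that the labels do not settle. As not every pair exceeded 0.1, the libraries were not treated as paired. Noisy libraries that are truly paired could also miss that bar, so pairing was not excluded.

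On library totals the median of a list changed sign in 12 cases. In Achilles against supraspinatus these were other collagens (-0.127 to 0.269), matrix glycoproteins (-0.112 to 0.284), ligands (-0.123 to 0.257) and osteoblast markers (-0.0768 to 0.323). In flexor against supraspinatus they were proteases (-0.157 to 0.184), cell cycle genes (-0.157 to 0.169) and pericyte markers (-0.011 to 0.347), and in patellar against supraspinatus other collagens (-0.0989 to 0.299) and immediate early genes (-0.399 to 0.032). Between the limbs they were other collagens (0.06 to -0.19) and Wnt genes (0.124 to -0.116), and in Achilles against patellar proteases (0.000602 to -0.000717). Depth set a floor of 0.0293 to 0.0473 CPM.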

Other observations

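Both tests in this part were chosen after the pattern was seen. Col1a2 was listed at 237 ± 151 CPM in Achilles, 65.3 ± 18.8 in flexor, 119 ± 39.2 in patellar and 74.9 ± 15 CPM in supraspinatus tendon, far below Col1a1. The annotation behind the counts is not given in the sources used here, so what the Col1a2 counts measure is uncertain. An unnamed gene, AABR07015081.2, stood at 21230 ± 2800 CPM in patellar tendon, among the most abundant there.

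A set of 9 genes was switched between libraries of a tendon, with a gap of at least 3 on the log2 scale and both states in at least 3 tendons. Map2k3 was high in 1 library of each tendon (215 to 1009 counts against at most 26), and LOC108348074 in 4 Achilles, 1 flexor, 2 patellar and 3 supraspinatus libraries. If replicate numbers marked the same animals across tendons, states that belong to an animal would match, but 0 of 24 same-numbered pairs had the same state at all 9 genes, and they shared 5.17 genes on average against 5.31 for other pairs. The same 4 animals in every tendon, with the numbers in another order, would give each gene the same number of high libraries in all tendons, and only 1 of the 9 genes did. Both readings assume that the state of these genes belongs to the animal, which was not tested.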
